A study of Homo sapiens with 6 samples.

How the data were processed

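Total RNA of K562, ML2 and NB4 cells transduced with a lentivirus for GFP or GFP-SOX7 was labelled with biotin and hybridised to HuGene 1.0 ST arrays, per the labels and per the file headers. There were 6 arrays, 1 per line and treatment, and the values in the series' value table were taken as they stand. The authors deposited values for 33297 transcript clusters on a log2 scale, as the values' range and near-equal array medians (6.83 to 6.93) show. The background correction, the summarization and the normalization software are not given in the sources used here. The authors also deposited summary tables for each line and for 3 arrays against 3, with a signed fold change, an absolute fold change (a ratio) and a log2 fold change per cluster, per the file headers, and no p-values. The authors' deposited table for K562 lists 22729 clusters and the others list 28829. The 6100 clusters left out of it had a mean log2 signal of 3.91 in the K562 arrays, against 7.68 for the others. The log2 fold changes of the authors' deposited tables correlated across genes with the differences computed from the value table (r = 0.865 for K562, 0.948 for ML2, 0.953 for NB4 and 0.994 for 3 arrays against 3). SOX7 in NB4, for example, had a log2 fold change of 3.51 in the authors' deposited table and 3.23 from the value table.

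Gene names came from the symbols in the authors' deposited tables, brought up to date through a RefSeq gene table of the GRCh38.p14 assembly. Of the clusters, 19536 had 1 symbol, 2582 had several, 6711 had none and 4468 were not listed. Of the single symbols, 16103 were current, 2496 were updated and 937 were kept as in the file. Genes were named only from clusters with 1 symbol, and the cluster with the highest mean stood for a gene, giving 18530 genes. A gene was tested when its mean over the 6 arrays was at or above the 25th percentile of such clusters (log2 5.92), which left 13934 genes. The further 7403 clusters of that brightness without a single symbol were tested apart and 0 passed in limma. No coordinates are given, since the build behind the files is not stated in them.

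Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with the cell line as a block and GFP-SOX7 against GFP as the term of interest. The block comes from the cell line label. After subtraction of group means, the arrays of a line deviated together (r = 0.931, 0.909 and 0.901), while arrays of different lines had r between -0.679 and -0.161. The fit has 2 residual degrees of freedom per gene and borrows 6.38 from all genes. Each line and treatment has 1 array, and nothing in the labels speaks of repeat cultures. The p-values of genes thus rest on the spread of the effect between lines, moderated by the spread borrowed from all genes. Within a line, genes with a log2 difference of at least 1 were counted with no test. A list's median in a line was set against 10000 random lists of the same size matched on mean signal. The 24 gene lists, with 460 genes of which 370 were tested, were compared with other genes by camera (preset correlation 0.01, and estimated), and fry tested each list against no change. The lines were compared by contrasts of the same fit.

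The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Per direction, the rule took the 12 genes of largest mean change past the threshold with 1 direction in all lines, filled up with unpassed genes where fewer passed. It also took the 5 highest and 5 lowest genes of each line, up to 4 members per list and 6 genes per line. Genes with uncharacterised names were left out, 3 of them past the threshold. Other genes named in the text, the SOX family and the remaining genes past the threshold included, were chosen after their values were seen.

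The fit was tested on simulated data with the residual spread of the real one, for GFP-SOX7 against GFP over 13934 genes with 50 changed genes at each size. It recovered 12% of the genes changed by a log2 of 0.5, 94% of those changed by 1 and 100% of those changed by 2 or 3, with 4 false calls among 157. A list of 20 genes shifted by 0.3 gave a camera p of 1.7e-10, and one not shifted 0.844. The simulated genes varied independently. The simulation therefore does not test camera on lists whose members move together, such as the mitosis genes (estimated correlation 0.942). Alternatives were no block, quantile normalization, subtraction of array medians, no filter and a median filter, the mean of a gene's probe sets, a trended and robust eBayes, and each line left out. Genes at least 2 log2 units brighter in the GFP array of K562 than in that of ML2 or NB4 were set apart after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the names and drew the plots.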

Results

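Transcript levels were measured on Affymetrix whole-transcript arrays in 3 human leukaemia cell lines that received a lentivirus for either GFP or GFP-SOX7. SOX7 is a transcription factor of the SOX F group, and the series asks about its role as a tumour suppressor in acute myeloid leukaemia. K562 is an erythroleukaemic line from a blast crisis of chronic myeloid leukaemia, ML2 is a myelomonocytic line and NB4 is a promyelocytic line with the PML-RARA fusion. Each line gave 1 GFP array and 1 GFP-SOX7 array, so the groups held 3 arrays each, and the GFP array of the same line was each array's control. The median log2 signal per array lay between 6.83 and 6.93. Of 18530 genes with a symbol of their own, 13934 were bright enough to be tested. The number of arrays limits the precision. With all lines in the fit, a gene's p-value below rests on its spread between the 3 lines and on a spread pooled over genes. The gene's own spread has 2 degrees of freedom and the pooled one 6.38. A gene's small p-value therefore does not show that its changes in the 3 lines were alike. For a gene list, camera's p-value compares the members with other genes. A small one does not show that the lines agree.

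SOX7 itself was checked first. Its log2 signal was 8.02, 7.33 and 7.44 in the GFP arrays of K562, ML2 and NB4, and 10.77, 10.99 and 10.66 in the GFP-SOX7 arrays. The group means were 7.60 ± 0.37 and 10.81 ± 0.17 (SD, n = 3). The mean difference was 9.27-fold (log2 change 3.21 ± 0.17 limma SE, limma adjusted p = 2.18e-04), higher in 3 of 3 lines. A limma SE draws on a spread pooled over genes and is not the SE of the 3 changes. Without the cell line as a block the same difference had an adjusted p of 0.0887. The probe set does not tell the transgene's transcript from that of the cells' own gene.

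**Figure D1:**
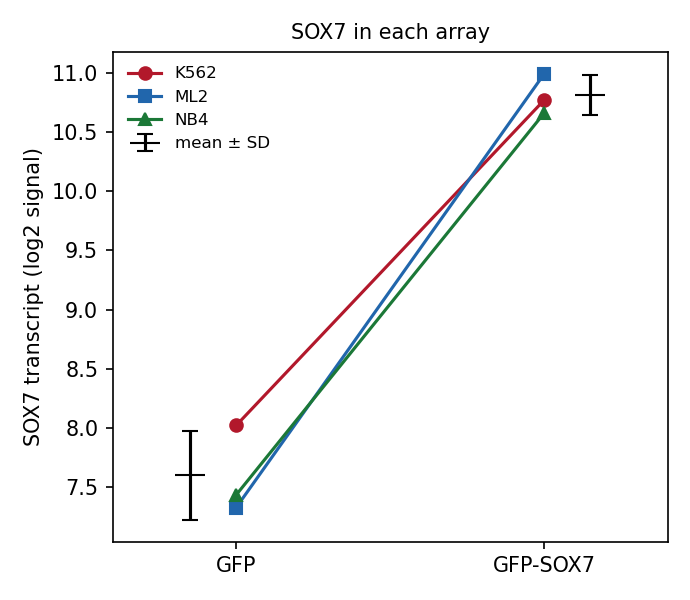
SOX7 transcript level (log2 signal) in the 6 arrays, with the GFP and GFP-SOX7 arrays of each line joined by a line and the group means ± SD (n = 3) beside them. The GFP arrays lie between 7.33 and 8.02 and the GFP-SOX7 arrays between 10.66 and 10.99.

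The main comparison asked which genes differed between GFP-SOX7 and GFP in all 3 lines together. Besides SOX7, 29 genes rose and 0 fell. The rise was largest for MOBP, which encodes a protein of oligodendrocyte myelin, at 6.74-fold (log2 change 2.75 ± 0.11 limma SE, n = 3, adjusted p = 5.09e-05). Next came the zinc finger gene ZC2HC1A at 5.16-fold (adjusted p = 0.00403), the membrane mucin MUC15 at 3.71-fold (adjusted p = 0.00113) and IL1A, the cytokine interleukin 1 alpha, at 3.67-fold (adjusted p = 0.00113). CACHD1, a gene related to calcium channel subunits, rose 3.29-fold, and the small GTPase RAB30 and the epithelial ETS factor EHF rose 3.14-fold and 3.13-fold. PELI1, a ubiquitin ligase of toll-like receptor signalling, rose 2.42-fold, the orphan receptor MRGPRE 2.41-fold and the antisense transcript GSN-AS1 2.48-fold. COBLL1 rose 2.57-fold with an adjusted p of 0.04998, just inside the threshold.

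All 29 genes were higher in each of the 3 lines, with mean rises from 1.69-fold (EPS8, an actin regulator) to 6.74-fold. Further transcription factors among them were THRB, a thyroid hormone receptor, at 2.03-fold (adjusted p = 0.029) and ZNF462 at 1.79-fold (adjusted p = 0.0388). CERS3, a ceramide synthase, rose 2.40-fold and SPRY3, a Sprouty family gene, 2.24-fold. Also past the threshold were CCDC81, PWWP3B, PALMD, KRTAP19-5, MAGEA12, TCEAL9, USP54 and 3 small nucleolar RNAs. All 30 genes including SOX7 had a GFP mean below the median of 8.07 over tested genes. Some, such as IL1A (5.06), EHF (5.24) and MOBP (5.89), lay below the filter of 5.92 in their GFP mean. Such genes were tested only through their GFP-SOX7 arrays, and a gene as dim that fell was not tested. With no filter on dim genes, 45 genes including SOX7 were higher and 0 lower. Of the 29 genes, 7 were at least 2 log2 units brighter in the GFP array of K562 than in that of ML2 or NB4, THRB, PALMD, TCEAL9 and COBLL1 among them.

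**Figure D2:**
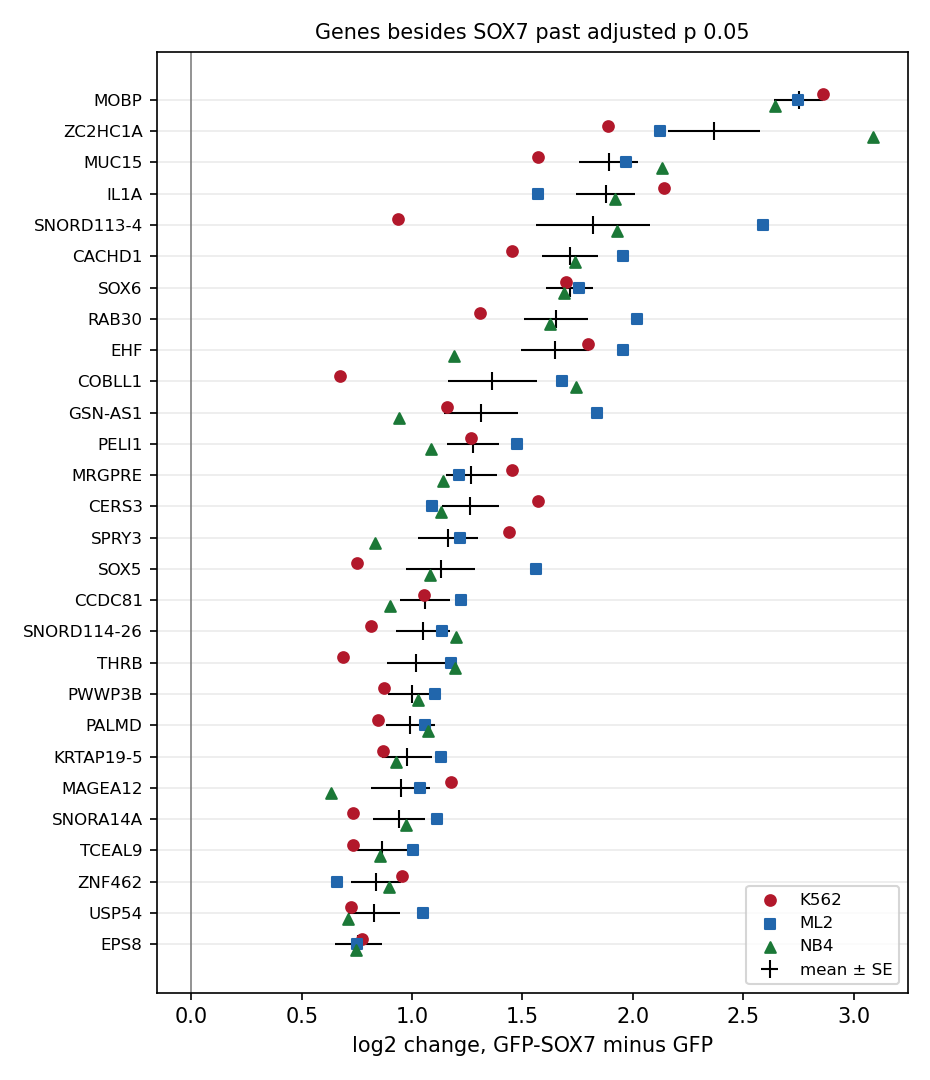
Log2 change (GFP-SOX7 minus GFP) of genes besides SOX7 past an adjusted p of 0.05, for K562 (circles), ML2 (squares) and NB4 (triangles). Bars give the mean over the 3 lines ± the SE of the limma fit. That SE draws on a spread pooled over genes and is not the SE of the 3 points. Every point lies above 0, with means from 0.76 (EPS8) to 2.75 (MOBP).

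No gene fell past the threshold in the limma fit, although 259 genes were lower and 549 higher at an unadjusted p under 0.05. The genes that came closest to a fall shared by the 3 lines had mean log2 changes of -0.61 (NIPSNAP3B, adjusted p = 0.102), -0.69 (the histone gene H2BC3, adjusted p = 0.123) and -0.90 (ART3, adjusted p = 0.192). ZNF618, FERMT1, ANKRD18A, PRSS12, RNF135, DDX60L, FSAF1, PHACTR2 and MRPS33 were also lower in all 3 lines, by means of -0.36 to -0.56, and none passed with all lines. Leaving out NB4 gave 158 genes higher and 22 lower, with H2BC3 (adjusted p = 0.00691), ART3 (0.00259) and RNF135 (0.0375) among the lower ones. Without NB4 the p-values rest almost wholly on a spread pooled over genes, so they do not show that K562 and ML2 agree. ART3, for example, changed by -0.36 in K562 and -1.47 in ML2. Leaving out K562 gave 127 higher and 6 lower, with ART3 (0.0219) among the lower ones. The number of genes past the threshold was 1 without the cell line as a block (MOBP), 133 without K562, 13 without ML2 and 180 without NB4. It was 3 with a filter at the median signal, which left only 6 of the 30 genes of the main fit to be tested. After quantile normalization it was 19, and it was 31 when genes far brighter in K562 were left out.

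Within the SOX family, the question was whether the added SOX7 moved its relatives. Of 17 SOX genes tested, 3 rose, namely SOX7, SOX6 and SOX5. SOX6, a SOX D factor of erythroid and cartilage development, rose 3.28-fold with changes of 1.70, 1.76 and 1.69 in K562, ML2 and NB4 (adjusted p = 6.18e-04). SOX5, also of the D group, rose 2.19-fold (adjusted p = 0.0394). Its adjusted p in limma was 0.0847 after quantile normalization and 0.185 without ML2. SOX18, of the same F group as SOX7, had a log2 change of 0.59 (adjusted p = 0.132, or 0.00266 adjusted over the list alone), and SOX13 of the D group one of 0.37 (adjusted p = 0.434, or 0.0248 adjusted over the list alone). SOX17, the remaining F group member, had a change of 0.14 (adjusted p = 0.989). The family was set out as a list after the values were seen.

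Within single lines, 1 array stood against 1 array, so the differences have no test, and SOX7 itself is left out of the genes named here. At a log2 difference of at least 1, K562 had 42 genes higher and 6 lower, ML2 had 179 and 36, and NB4 had 165 and 7. Besides SOX7, the highest in K562 were MOBP, IL1A, ZC2HC1A, EHF and SOX6. The lowest there were the interferon-stimulated gene RSAD2 at -1.57, UNC13A, EVI2B, SCN9A and LGALS1. Among the highest in ML2 were the coagulation inhibitor TFPI at 3.69, the growth factor AREG at 3.57, CWH43 at 3.45 and ERRFI1 at 3.44. The lowest in ML2 were the dehydrogenase gene DHRS9 at -1.86, the mitotic genes ASPM at -1.83, CENPE at -1.81 and KIF20B at -1.65, and SCHIP1 at -1.61. Among the highest in NB4 were the transcription factor TCF4 at 3.70, ZC2HC1A at 3.09, AREG at 3.06 and the sorting receptor SORT1 at 2.97. The lowest in NB4 were SERPINB8 at -1.76, USP17L6P, the ectonucleotidase ENTPD1 at -1.36, MNDA and ANKRD22.

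Most of the genes that were higher in ML2 and NB4 were genes that K562 expresses. Of the 179 genes higher in ML2, 127 (70.9%) were at least 2 log2 units brighter in the GFP array of K562 than in that of ML2, against 2.92% of tested genes. The corresponding number in NB4 was 106 of 165 (64.2%), against 3.01%. TFPI, AREG, CWH43 and ERRFI1 in ML2 and TCF4, AREG and SORT1 in NB4 were among them. A line's GFP array both sets this class and is subtracted for the change, so part of the excess is built in. In ML2, 34.3% of genes at least 2 log2 units brighter in NB4 than in both other lines rose by over 0.3. The share was 77.9% for genes so chosen in K562 and 13% for tested genes. Over the 262 genes that were 2 log2 units brighter in K562 than in both other lines, the median log2 change was 0.05 in K562, 0.64 in ML2 and 0.55 in NB4. Without the genes brighter in K562, 52 genes were higher and 36 lower in ML2, and 59 higher and 7 lower in NB4.

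**Figure D3:**
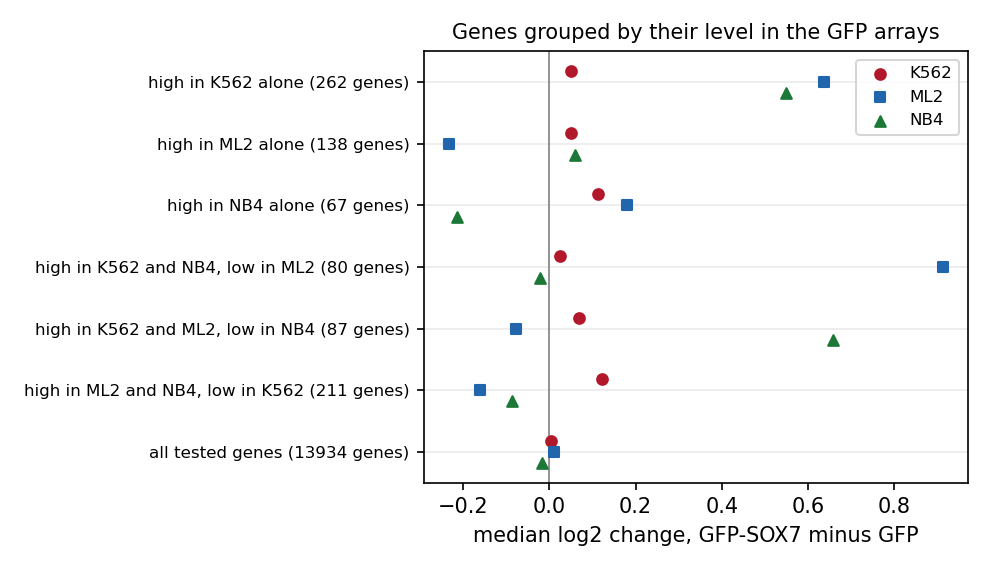
Median log2 change (GFP-SOX7 minus GFP) in K562 (circles), ML2 (squares) and NB4 (triangles) of genes grouped by which GFP arrays showed them at least 2 log2 units brighter. The 262 genes high in K562 alone have medians of 0.64 in ML2 and 0.55 in NB4, and the 80 genes low in ML2 alone have a median of 0.91 in ML2.

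The agreement between lines was limited to part of the genes. A gene went the same way in all 3 lines for 24.3% of tested genes, where 25% is expected by chance. Across genes, which are not independent replicates, the changes correlated between ML2 and NB4 (Pearson r = 0.379, Spearman rho = 0.252) and hardly between K562 and ML2 (r = 0.047, rho = -0.0833) or K562 and NB4 (r = 0.0139, rho = -0.112). Without genes brighter in K562 the first pair had r = 0.218 and rho = 0.221. ML2 and NB4 had 85 higher genes in common, where independent lists of that length would share 2.12. Of these, 65 were brighter in K562 than in both lines, and 12 were also at least 1 log2 unit higher in K562 with SOX7.

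The direct question on SOX7 as an opponent of Wnt/beta-catenin signalling was addressed with 17 tested target genes of that pathway. None of them passed over all genes, and their mean log2 change was 0.10 with a median of 0.03 (camera adjusted p = 0.0911, 0.572 with an estimated correlation). The transcription factor gene JUN had a change of 0.81 and LEF1 one of 0.44, both positive in 3 of 3 lines and under 0.05 only when adjusted over the list alone (0.00932 and 0.0458). LEF1 was brighter in the GFP array of K562 than in those of ML2 and NB4. RNF43 had a change of 0.31 and TCF7 one of 0.23. Averaging a gene's probe sets took the list to an adjusted p of 0.044. Among 26 Wnt pathway components, 0 passed and the largest mean change was that of the receptor gene FZD3 at 0.81, which came from ML2 (2.26) and is a gene low in ML2 and high in the other lines.

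Of 24 gene lists, camera's preset correlation placed 6 higher and 3 lower than other genes. With a correlation estimated from the data it placed 0, and the smallest adjusted p was 0.572. With GFP and GFP-SOX7 swapped in ML2, NB4 or both, the preset test still passed 8 lists. Its calls alone thus do not show an effect of SOX7. No list passed fry's test of a shared direction or of change in either direction. No member of any list passed over all genes. The erythroid genes led the higher lists (9 tested, 8 positive, mean 0.79, adjusted p = 2.52e-12, adjusted p = 0.572 with an estimated correlation), and 8 of them passed when adjusted over the list alone. GYPB, a glycophorin, had changes of -0.10, 1.85 and 2.49 in K562, ML2 and NB4, and the Rh-associated glycoprotein gene RHAG had -0.08, 2.07 and 2.02. The embryonic globin genes HBE1 and HBZ had mean changes of 1.13 and 0.87, and HBZ was also higher in K562 itself, by 1.26. The same held for the haem synthesis gene ALAS2, with a change of 0.56 in K562. All 8 positive members were at least 2 log2 units brighter in the GFP array of K562 than in those of ML2 and NB4, and 1 member was left without such genes. Without the cell line as a block the list had an adjusted p of 0.135, and with no filter on dim genes its mean was 0.49.

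Glycolysis and hypoxia genes were positive in 18 of 18 tested members (mean 0.40, adjusted p = 5.05e-09, adjusted p = 0.572 with an estimated correlation). BNIP3, a mitophagy receptor, had a mean change of 1.10 (adjusted p = 0.0601, 0.00263 adjusted over the list alone), and it was brighter in the GFP array of K562 than in that of ML2. The aldolase gene ALDOC at 2.29, PFKFB4 at 2.09 and the enolase gene ENO2 at 1.65 were high in NB4, against -0.08, -0.07 and 0.54 in ML2. Without NB4 the list's mean was 0.16 (adjusted p = 0.0122). NF-kB and inflammatory genes were positive in 14 of 16 (mean 0.24, adjusted p = 1.81e-04, adjusted p = 0.572 with an estimated correlation), and 4 passed when adjusted over the list alone. The chemokine gene CXCL8 had a mean change of 0.82, TNFAIP3 one of 0.54, the adhesion gene ICAM1 one of 0.49 and IER3 one of 0.41. This list had an adjusted p of 0.0695 without the block, and a mean of 0.14 without NB4 (adjusted p = 0.0412). Immediate early genes were positive in 17 of 18 (mean 0.21, adjusted p = 6.42e-05, adjusted p = 0.572 with an estimated correlation), led by EGR1 at 2.32 in ML2 and -0.21 in K562, a gene brighter in the GFP array of K562 than in that of ML2. Their mean was 0.09 without ML2 (adjusted p = 0.188) and 0.35 without K562. Stress genes of the unfolded protein and amino acid responses were positive in 15 of 19 (mean 0.22, adjusted p = 0.00282, adjusted p = 0.572 with an estimated correlation). CTH, TRIB3 and ASNS among them were higher in ML2 by 1.72, 2.36 and 1.24, and TRIB3 and ASNS were lower in NB4 by -0.69 and -0.64. This list had a mean of 0.04 without ML2 (adjusted p = 0.427) and 0.38 without NB4. Fibroblast and epithelial genes, which mark cells other than those cultured, were positive in 7 of 7 (mean 0.16, adjusted p = 0.0139, adjusted p = 0.572 with an estimated correlation), led by the keratin genes KRT18, KRT19 and KRT8 at 0.32, 0.32 and 0.28, which were brighter in the GFP array of K562 than in that of ML2. Their adjusted p was 0.375 without genes brighter in K562, 0.261 without ML2, 0.0866 without NB4, 0.0812 with no filter on dim genes and 0.243 without the block.

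The lower lists were those of the cell cycle and ribosome production. Mitosis genes were negative in 18 of 19 (mean -0.23, adjusted p = 3.01e-05, adjusted p = 0.593 with an estimated correlation), with medians of 0.02 in K562, -0.56 in ML2 and -0.06 in NB4. CENPE, CENPF and KIF20A, which act in cell division, had changes of -1.81, -1.47 and -1.15 in ML2. Without ML2 the list's mean was 0.00 with an adjusted p of 0.941, and without K562 it was -0.37. DNA replication genes were negative in 21 of 22 (mean -0.16, adjusted p = 3.52e-05, adjusted p = 0.572 with an estimated correlation), with MCM5 at -0.35, GINS2 at -0.33 and MCM7 at -0.27. Their medians were -0.32 in ML2, -0.27 in NB4 and 0.08 in K562, and their mean was -0.09 without ML2 (adjusted p = 0.188) and -0.27 without K562. Ribosome biogenesis genes were negative in 11 of 15 (mean -0.10, adjusted p = 0.032, adjusted p = 0.623 with an estimated correlation), with RRP12 at -0.26, and UTP20 and WDR12 at -0.22 each. Their mean was -0.01 without ML2 (adjusted p = 0.93), -0.07 without NB4 (0.127) and -0.22 without K562 (3.32e-04). The adjusted p was also over the threshold after quantile normalization (0.0784), with a median filter (0.0729) and without the block (0.141).

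**Figure D4:**
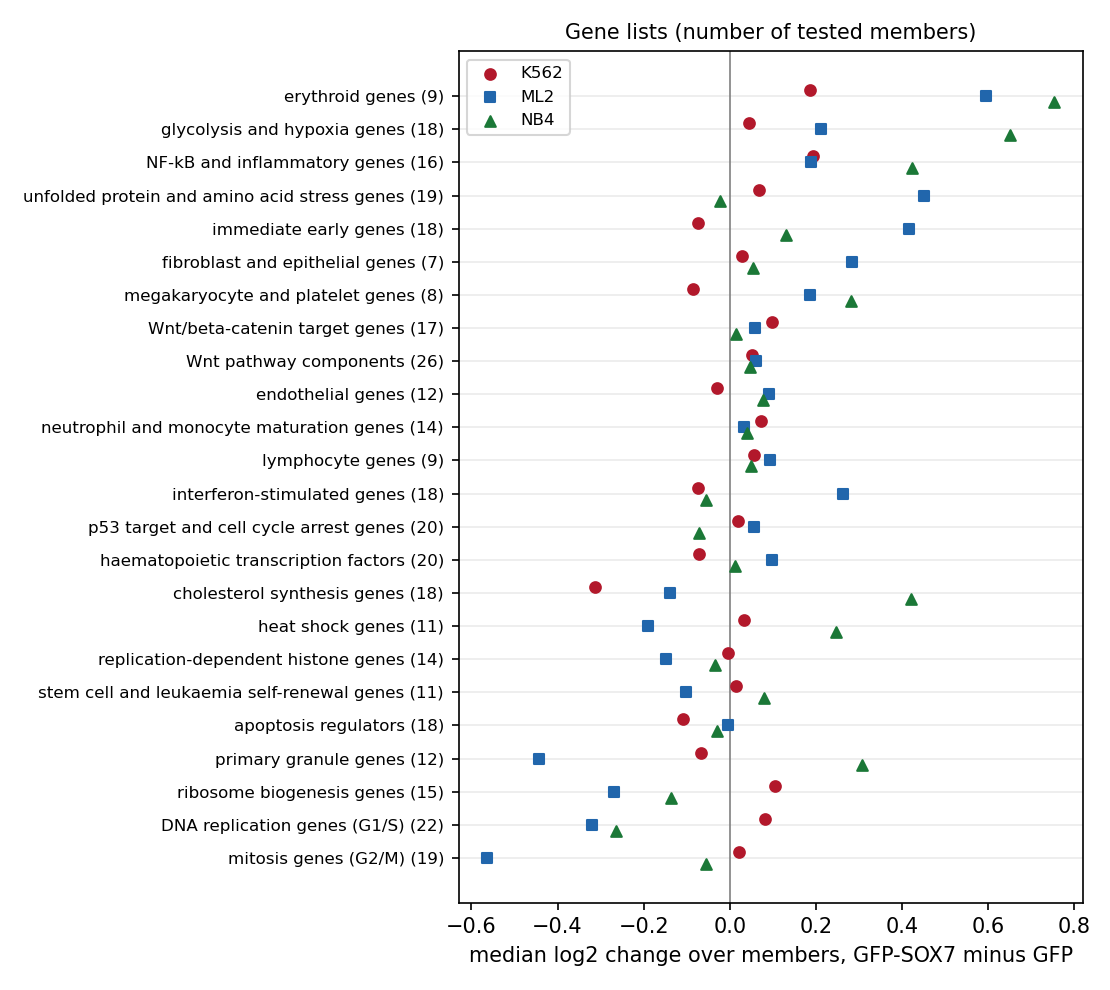
Median log2 change (GFP-SOX7 minus GFP) over the tested members of each gene list, for K562 (circles), ML2 (squares) and NB4 (triangles), ordered by the mean over lines. Erythroid genes lie at 0.19, 0.60 and 0.75 in the 3 lines, and mitosis genes at 0.02, -0.56 and -0.06.

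The other lists did not pass, though some passed under another setting. Endothelial genes had an adjusted p of 0.202 and a mean of 0.08, with the Notch target HEY1 at 0.47 under 0.05 when adjusted over the list alone (0.0429). Histone genes had an adjusted p of 0.156, with H4C8 at 1.18, which was brighter in K562, and H2BC3 at -0.69 (0.00775 adjusted over the list alone). Haematopoietic transcription factors (adjusted p = 0.468), neutrophil and monocyte maturation genes (0.202), megakaryocyte and platelet genes (0.101), stem cell and self-renewal genes (0.466), p53 targets (0.689), apoptosis regulators (0.156), interferon-stimulated genes (0.202) and lymphocyte genes (0.202) had means between -0.05 and 0.11. The stem cell list had a mean of -0.05 and a median of 0.01. The Wnt pathway components had an adjusted p of 0.128. Primary granule genes had an adjusted p of 0.107 and a mean of -0.08, heat shock genes 0.866 and 0.00. Cholesterol synthesis genes had a mean of 0.01 and a median of 0.04 while camera placed them lower (adjusted p = 0.99). Without NB4, camera placed primary granule genes (mean -0.26, adjusted p = 8.65e-06), cholesterol synthesis genes (mean -0.21, adjusted p = 8.65e-06) and stem cell genes (adjusted p = 0.0412) lower and interferon-stimulated genes higher (0.0412). Megakaryocyte genes passed as higher without K562 (0.00717) and without genes brighter in K562 (0.0446), endothelial genes with no filter (0.0205), and Wnt components and neutrophil genes with a median filter (0.0139 and 0.0331). All of these rest on the preset correlation, and with an estimated one, all lines and the usual filter these lists had adjusted p-values from 0.572 to 0.997. Subtracting each array's median turned the sign of the means of heat shock genes, cholesterol synthesis genes and haematopoietic transcription factors.

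The lines themselves differed far more than the treatments. In the same fit, 5701 genes differed between K562 and ML2, 5045 between K562 and NB4 and 4002 between ML2 and NB4, of 13934 tested. K562 stood apart by the glycophorin gene GYPB, the globin genes HBZ and HBE1, CD24, CPED1 and DSG2, each at least 4.88 log2 units above both other lines. ML2 stood apart by the antigen presentation gene HLA-DRA at 6.03, the defensin gene DEFA4, ALOX5AP, BEX1, the monocyte factor IRF8 and the cyclin gene CCNA1. NB4 stood apart by LIN7A at 4.55, PTPN13, SERPINE2, IL23R and RHEX. Each of these passed against both other lines (largest adjusted p 3.03e-04, for CPED1). A line's arrays, 1 per treatment, served as its replicates here.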

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

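All tests of explanations in this part were chosen after the results were seen, except the counts of other splits. One line's change was set against those of the other lines (limma on the within-line changes, 1 residual degree of freedom, added after the data were seen), which assumes that the lone line varies like the others. Past the threshold were 27 genes for K562, 3 for ML2 and 90 for NB4, but a call depends on how close the other lines happen to lie, so these genes are not shown to be specific to a line. The 27 genes, CWH43 and SORT1 among them, all had the lower change in K562, and all were far brighter in K562. The 3 genes of ML2 were ANXA5, ORM1 and ERRFI1, higher there by 3.22, 3.10 and 3.44 on the log2 scale, and ANXA5 and ERRFI1 were far brighter in K562 than in ML2. Of the 90 genes of NB4, 63 had the higher change there, among them H19, ALDOC and, far brighter in K562 than in NB4, TCF4, LAPTM4B and NRIP1. Haematopoietic transcription factors had a median change of 0.0985 in ML2 and -0.071 in K562, primary granule genes 0.307 in NB4 and -0.442 in ML2, and cholesterol synthesis genes 0.422 in NB4 and -0.312 in K562. These medians lay in opposite tails of random lists, and the difference between the lines was not tested for them.

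Genes high in K562 were higher in the GFP-SOX7 arrays of ML2 and NB4. Selection on the GFP arrays is argued against as the whole cause. Genes chosen as low in K562 had a median change of 0.121 there. Genes low in ML2 alone had 0.913 in ML2 and genes low in NB4 alone 0.659 in NB4. These last groups are high in K562 by definition. Changes in K562 were also less spread (SD 0.224, against 0.34 in ML2 and 0.307 in NB4). In ML2, genes high in K562 alone had 0.638 and genes high in NB4 alone 0.179, though both groups were chosen as low there. A part played by selection stays open, since 25.6% of genes low in K562 rose by over 0.3 there, against 8.16% of tested genes. RNA of K562 cells in the GFP-SOX7 samples of ML2 and NB4 may be the source. Genes high in K562 alone exceeded genes high in the third line alone by at least 0.46 in both lines. The share of K562 RNA that each of 132 genes implies had a median of 5.67% in ML2 and 4.71% in NB4. The 90th percentile was at least 3.12 times the median in both. It was 17.7% in ML2, where a simulated mix of 5% gave 6.28%. The simulation added noise to the mixed array alone, so its spread is narrower than that of real arrays would be. A gene's shares in ML2 and NB4 went together (Spearman rho = 0.9), both resting on the same K562 array. The spread of the shares argues against 1 share of RNA with that array's profile as the whole cause. How far the shares would spread under 1 share in real arrays was not measured. K562 RNA as a source stays open, because the K562 profile had to be assumed. In ML2 the shares ran from 0.683% (HBZ) and 3.05% (HBE1), both abundant in K562, up to 59.1% (AREG). That SOX7 raised genes K562 already expresses also stays open, untested.

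For the 29 genes higher in all 3 lines, RNA of K562 cells in the ML2 and NB4 samples would have to make up 73.1% and 60.9% of the RNA for the median of these genes, against 5.67% and 4.71% for genes high in K562, and 8 of the 29 had a higher GFP-SOX7 level in ML2 or NB4 than in K562, which speaks against it as the whole cause. Nor could such RNA raise the genes in K562 itself, where their smallest change was 0.672, though they were picked for rising there. For the rises in ML2 and NB4 it is not excluded, because the K562 array had to stand for that RNA and the genes were picked for rising in all lines. Transgene RNA on probes of similar genes was expected to raise SOX17 and SOX18, the closest relatives, at least as much as SOX5 and SOX6. That expectation was not met, with a mean change of 0.363 against 1.42 for SOX5 and SOX6. It does not decide the question, because the probes' places in the transcripts are not given. Transgene RNA thus cannot be told here from a rise of the transcripts of SOX5 and SOX6. An effect of SOX7 on these genes stays open, and the splits are too few for a share under 0.05, both with the block (1 of 4 swaps within lines with as many, 30 genes in the real one, 0 in the highest other) and without it (1 of 10 splits, 1 gene against 0).

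Mitosis genes were lower in ML2, by a median of -0.564, with 19 of 19 negative. Dilution by K562 RNA is argued against as the cause: genes high in ML2 alone, which it would lower most, had a 25th percentile of -0.49 and a median of -0.233, and all 19 mitosis genes lay below that median. An effect of SOX7 in ML2 and the growth state of that culture stay open, since it was 1 array against 1. Over all lists, swapping within lines gave 8 lists past camera's preset test in each other split. The real one had 9 (1 of 4 as large). The preset test passed nearly as many lists with the treatment labels swapped, so the 9 calls alone do not show an effect of SOX7. The splits are too few for a share under 0.05.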

How the results depend on the processing

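Without the cell line as a block, 1 gene passed instead of 30 and the SOX7 transcript (log2 3.212) had an adjusted p of 0.0887, while K562 minus ML2 and the other line contrasts need the cell line and were not run that way. The same setting ended the calls of erythroid genes (adjusted p = 0.135), NF-kB genes (0.0695), ribosome biogenesis genes (0.141) and fibroblast and epithelial genes (0.243). Genes changed by SOX7 numbered 19 after quantile normalization and 3 with a median filter, which left only 6 of the 30 to be tested. They numbered 73 at an unadjusted threshold with a log2 change of at least 1, and 13 to 180 with a line left out. The other settings left between 26 and 45. Wnt target genes reached a mean of 0.1127 (adjusted p = 0.044, over all settings 0.044 to 0.572) with the mean of a gene's probe sets. Counts within K562, ML2 and NB4 were 261, 764 and 591 at 1.5-fold and 26, 126 and 106 in the authors' tables, and without genes high in K562 they were 88 in ML2 and 66 in NB4. Genes of 1 direction in all lines made up 25.49% with no filter, and with a line left out 44.62% to 58.8%, where chance is 50%. An estimated correlation ended all 9 list calls. With array medians subtracted, the list means of haematopoietic transcription factors, heat shock genes and cholesterol synthesis genes became -0.001638, -0.02673 and -0.01705, and with a median filter that of cholesterol synthesis genes became -0.01128. Without genes high in K562, a setting chosen after seeing the data, erythroid genes had -0.106, p53 targets -0.00947, heat shock genes -0.0117 and cholesterol synthesis genes -0.0138. With a line left out, list means ran from -0.02447 to 0.06173 (haematopoietic transcription factors), -0.2622 to 0.09582 (primary granule), -0.1285 to 0.00626 (stem cell), -0.3705 to 0.001348 (mitosis), -0.07315 to 0.1348 (interferon), -0.05991 to 0.07414 (heat shock, -0.0009868 without K562), -0.213 to 0.1583 (cholesterol) and -0.0733 to 0.01455 (histone). Of the values of the lists other than the Wnt targets, 227 led to the same reading, 24 were weaker, 8 stronger and 17 of the other sign. Of the named genes' values 306 stayed, 70 were weaker and 4 stronger. A list or gene that failed in the main fit and failed again counts as the same, so these tallies do not measure how stable the calls were. The number kept of the 30 genes of the main fit ran from 1 without the block to 30 without NB4. The cause of the differences between settings was not tested. The authors' 3 against 3 table holds no p-values, so its threshold was not run.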

Other observations

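The values in this part were all picked out after they were seen. In the single pair of NB4 arrays, some further genes were higher with SOX7. Metallothionein genes MT1X and MT1F were higher by 1.57 and 1.39, the chemokine gene CCL2 by 1.75 and the imprinted transcript H19 by 1.99, while K562 had -0.53 for CCL2 and -0.28 for H19. The eosinophil and granule genes RNASE2 and DEFA4 were higher by 1.30 and 1.39 in NB4 and lower in ML2 by -0.70 and -0.51. Sterol genes CYP51A1 and INSIG1 were higher by 1.28 and 1.01 in NB4 and at -0.30 and -0.34 in K562. CCL2 and CYP51A1 were brighter in the GFP array of K562 than in that of NB4, and the others were not. All of these are differences of 1 array against 1 array.

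Of the 262 genes high in K562 alone, 254 were not on the list of erythroid genes, which does not hold all such genes, and had a median change of 0.64 in ML2 and 0.54 in NB4, and the 8 erythroid genes had 0.93 and 0.88.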
